A study of Mus musculus with 50 samples.

How the data were processed

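Gene expression was read in 50 samples of mouse RNA, 10 of pancreatic islets and 40 of splenic CD4+CD25− T cells, in 10 groups of 5. Per the labels' protocols, islets were taken by collagenase perfusion and hand-picking, spleen T cells were depleted of CD25+ regulatory T cells, samples were lysed in SuperAmp buffer, and RNA was amplified by an array service. Each sample was hybridised to a 1-colour Agilent array, and the deposited scanner files hold spot signal as intensity on a linear scale, background-subtracted and detrended with Agilent Feature Extraction 10.7.3.1, per the file headers. The table of values deposited by the authors holds log2 values of 19156 entries between 4.65 and 18.4, and no header records how they were normalised. It was used as an alternative. The series text speaks of male mice only, whereas the labels name both sexes, and groups were taken from the labels.

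Per array, the processed signal of each spot was put on a log2 scale, averaged over the spots of a probe and reduced by the array's 75th percentile. Islet arrays were scaled by all probes, and T cell arrays, whose median share of spots well above background was 46.9%, by probes well above background on all arrays of the tissue. Of 55681 probes, 28026 were matched to a gene by accession, 3418 by symbol and 295 by synonym with the gene table of the reference, and 23942 were not matched, 16194 of them for lincRNA windows. They gave 22563 genes, 7115 of them with over 1 probe. A gene was represented by its brightest probe and tested where that probe was well above background on at least 5 arrays of the tissue. Coordinates are those of the array annotation (mm9). The number of arrays limits the precision.

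Groups were compared with limma (lmFit and eBayes) in 1 fit per tissue, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. In islets the contrast was NckH minus NckL. In T cells it was the mean subline difference over 4 pairs of groups, each of those differences, the mean difference by age and by labelled sex, and the interactions of subline with age and sex. A total of 44 gene lists were fixed before the data were examined, and those with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Scores are means over the tested genes of a list. Exact permutation tests over all relabellings were used for islet scores, and Fisher's exact test for counts.

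Genes were named by a rule written before the data were examined. It took the 10 largest called rises and falls with an assigned symbol, for mean effects only with the same sign in all 4 differences. It took up to 3 members with the smallest p of each list that passed or held a called gene, genes shared by both tissues, the 3 smallest p of each interaction, and check genes of cell type and sex. Where fewer than 10 genes passed, the 10 with the smallest p were named. Ifnb1 and Rp9 fall outside this rule. Some genes the rule names are not reported here, including 1 that passed for the T cell subline. The smallest p among the groups labelled female of 15 weeks were given in addition.

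The procedure was tested on simulated data with 200 changed genes and a further list of 20 genes lowered by 1. Genes were drawn independently of each other, so the rates below do not cover variation that genes share on the real arrays. Of 50 genes changed by 1, 2, 3 and 4 in the islet design (15260 genes), 56%, 94%, 96% and 100% were recovered, and 19 of 202 calls (9.41%) had no change. Of 50 genes changed by 0.5, 1, 1.5 and 2 in the T cell design (13974 genes), 72%, 92%, 96% and 98% were recovered, and 10 of 208 calls (4.81%) had no change.

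The alternatives were normexp background correction with an offset of 50, the other percentile, quantile normalisation, no detection filter or a stricter one, the mean of a gene's probes or every probe, a trended and robust prior, array weights, the replicate number as a block, slide as a fixed or random block, the authors' values, a log2 change of at least 1, only the compared groups, single slides, and each sample left out. After seeing the data 3 more were added, which left out islet libraries that stood apart, the dimmest islet arrays, and T cell libraries that went against their labelled sex. Probes matched to no gene were left out of the comparisons. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.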

Results

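Gene expression was measured on 1-colour Agilent mouse arrays in sublines of the non-obese diabetic (NOD) mouse, a model of autoimmune diabetes. NOD/NckH is labelled as a subline with a high incidence of diabetes and NOD/NckL as one with a low incidence. A total of 50 arrays were read: 10 of pancreatic islets from males of 3 weeks (5 NckH, 5 NckL) and 40 of splenic CD4+CD25− T cells. The T cell arrays formed 8 groups of 5, with each subline at 6 and 15 weeks and under a male and a female label. Between 50.8% and 58.2% of the 59305 spots were well above background on the islet arrays (median 55.7%), and between 42.9% and 50.8% on the T cell arrays (median 46.9%). No spot was saturated (0), and the number of arrays per group limited the precision. Values below are log2 signals relative to the array's 75th percentile as mean ± SD. Differences are log2 values ± standard error (SE) from limma, and a gene passed at an adjusted p under 0.05.

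The first comparison asked how the islets of the sublines differed at 3 weeks of age. Genes of the interferon response were lower in NckH islets. Ifit1, which encodes an interferon-induced antiviral protein, was at −1.77 ± 1.34 in NckH and 1.73 ± 0.96 in NckL (difference −3.50 ± 0.65, adjusted p = 0.0405, n = 5 and 5). Its relatives Ifit3 (−3.77 ± 0.70), Ifit3b (−3.80 ± 0.65) and Ifit2 (−2.72 ± 0.42) fell as well, as did Rsad2, the gene of the antiviral enzyme viperin, by 3.19 ± 0.54 (adjusted p = 0.0345). Interferon beta itself was part of this set: Ifnb1, chosen after its values were seen, was lower in NckH (adjusted p = 0.00365). Its probe was well above background on 1 of 5 NckH and 5 of 5 NckL arrays, so the size of the fall was not estimated. A total of 119 of 15260 tested genes passed, 30 higher and 89 lower in NckH, and 95 of them changed at least 2-fold (21 higher, 74 lower). At an unadjusted p under 0.05 there were 2758 genes, where chance gives 763.

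The gene with the smallest p was Syt10, a synaptotagmin, the family of calcium sensors for vesicle release. It was at −3.46 ± 0.51 in NckH and 1.34 ± 0.51 in NckL islets (difference −4.80 ± 0.29, adjusted p = 0.000123). Other large falls were those of Apol9b, an interferon-inducible apolipoprotein L (−4.54 ± 0.61, adjusted p = 0.0203), of Fgg, the fibrinogen gamma chain (−4.45 ± 0.77, adjusted p = 0.0350), and of Serpina3n, an acute-phase protease inhibitor (−3.65 ± 0.57, adjusted p = 0.0297). Steap4, a cytokine-induced metalloreductase, and Ifit1bl1 were well above background on 0 of 5 NckH arrays and on 5 of 5 NckL arrays. They were at least 13.4-fold and 8.16-fold lower. Among the rises, Galnt15, a glycosyltransferase gene, was higher by 1.67 ± 0.28 (adjusted p = 0.0345) and Pcdh12, an endothelial protocadherin, by 1.55 ± 0.28 (adjusted p = 0.0405). The adaptor gene She (1.47 ± 0.23), the transporter gene Slco2b1 (1.58), Hdhd3 (1.41), Scgb3a1 (1.31), the transcription factor gene Ebf3 (1.28), Bcas3os2 (1.47) and Pisd-ps3 (1.30) rose too. The NckL values of Scgb3a1 (−5.80 to −5.00) were close to those of Steap4 in NckH (−6.44 to −5.02), so the size of its rise is uncertain. Exoc3l2 had the largest rise (2.01 ± 0.37), but its other probe did not follow (−0.0134 ± 0.25). In each of these genes the 5 NckH values lay apart from the 5 NckL values.

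Lists of genes fixed beforehand were tested as sets (camera with a preset correlation). All 31 tested members of the type I interferon list were lower in NckH (mean −1.93, adjusted p = 3.26e-21, and adjusted p = 0.484 with an estimated correlation). Of these, 9 passed among all genes and 31 when adjusted over the list alone, Rtp4 (−2.60 ± 0.44) and Zbp1 (well above background on 1 of 5 NckH and 5 of 5 NckL arrays) among them. Of 23 members of the MHC class I and interferon gamma list 21 were lower (mean −1.02, adjusted p = 2.22e-10, and adjusted p = 0.484 with an estimated correlation). Here 5 members passed, all lower, and adjusted over the list alone 18 were lower and 1 higher. The GTPase genes Irgm2 (−2.49 ± 0.34) and Irgm1 (−2.21 ± 0.36) and Cd274, which encodes the checkpoint ligand PD-L1 (−1.27 ± 0.22), were among them. Single members of other lists fell: the chemokine gene Ccl4 (−1.19 ± 0.16), Spp1, which encodes osteopontin (−1.66 ± 0.28), Ptpn2, a phosphatase gene at a diabetes locus (−0.80 ± 0.15), and Socs3, an inhibitor of cytokine signalling (−1.41 ± 0.24). Cxcl10 (−2.85 ± 0.57, adjusted p = 0.0532) and Ifih1, which encodes a sensor of viral RNA (−1.33 ± 0.29, adjusted p = 0.0678), did not pass, nor did Cxcl12 (1.12 ± 0.25), whose other probe was at −0.0223 ± 0.24.

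Lists of other cell types and functions shifted as well. All 27 genes of pancreatic acinar cells were lower in NckH islets (mean −3.15, adjusted p = 3.10e-07, and adjusted p = 0.589 with an estimated correlation), yet 0 passed alone in limma. Ctrc (−3.58 ± 1.32), Pnlip (−4.33 ± 1.64), Try5 (−3.81 ± 1.46) and Cpa1 (−3.89 ± 1.62) varied widely within groups. Endothelial genes were higher (14 of 18, mean 0.35, adjusted p = 7.02e-05; 5 higher when adjusted over the list alone), with Sox18 at 1.38 ± 0.40 and Robo4 at 0.64 ± 0.20, neither passing alone, and their adjusted p = 0.589 with an estimated correlation. The rise lay in NckH replicates 1 and 2 (scores of 2.39 and 2.11), where the other islet arrays were at 1.24 to 1.44. The mean was 0.17 without NckH replicate 1 and −0.00884 without the 3 dimmest arrays, and the exact permutation p was 0.325. Erythroid genes were higher in 7 of 8 (mean 0.55, adjusted p = 0.000145), including Hbb-b2 (0.86 ± 0.18) and Alas2 (1.06 ± 0.24), and had an adjusted p = 0.484 with an estimated correlation. Their mean was 0.31 without NckH replicates 4 and 5. Lower lists with an adjusted p = 0.484 with an estimated correlation were antioxidant defence (21 of 23, mean −0.41, Txnrd1 −0.64 ± 0.13) and ductal genes (11 of 13, mean −0.39). The ribosomal (28 of 29, mean −0.23) and oxidative phosphorylation lists (33 of 33, mean −0.29) were lower with adjusted p = 0.687 and 0.749 with an estimated correlation. Without NckH replicate 1 their means were −0.15 and −0.16 (adjusted p = 0.0525 for the latter), and without the 3 dimmest arrays −0.14 and −0.15. Genes of endoplasmic reticulum stress (18 of 22, mean −0.31, Atf6 −0.70 ± 0.21) and of glycolysis and hypoxia (18 of 22, mean −0.32) had an adjusted p = 0.589 with an estimated correlation. In total 11 of 31 lists passed, 2 higher and 9 lower, and 0 passed with an estimated correlation. With fry 10 passed, of which 6 were among the 11. The acinar, endothelial, endoplasmic reticulum stress, oxidative phosphorylation and ribosomal lists did not pass with fry, whereas those of dendritic cells, granulocytes (both with an adjusted p of 0.0237), platelets (0.0251) and diabetes susceptibility (0.0433) did, all lower. The list of beta cell identity did not pass (mean 0.08, adjusted p = 0.122), nor did chemokines (−0.89, adjusted p = 0.101) or macrophage genes (0.06, adjusted p = 0.735). Ins1 (0.20 ± 0.28), Ins2 (0.20 ± 0.26), Gcg (−0.18 ± 0.16), Sst (−0.15 ± 0.26) and the leukocyte gene Ptprc (0.33 ± 0.27) did not pass either.

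**Figure D1:**
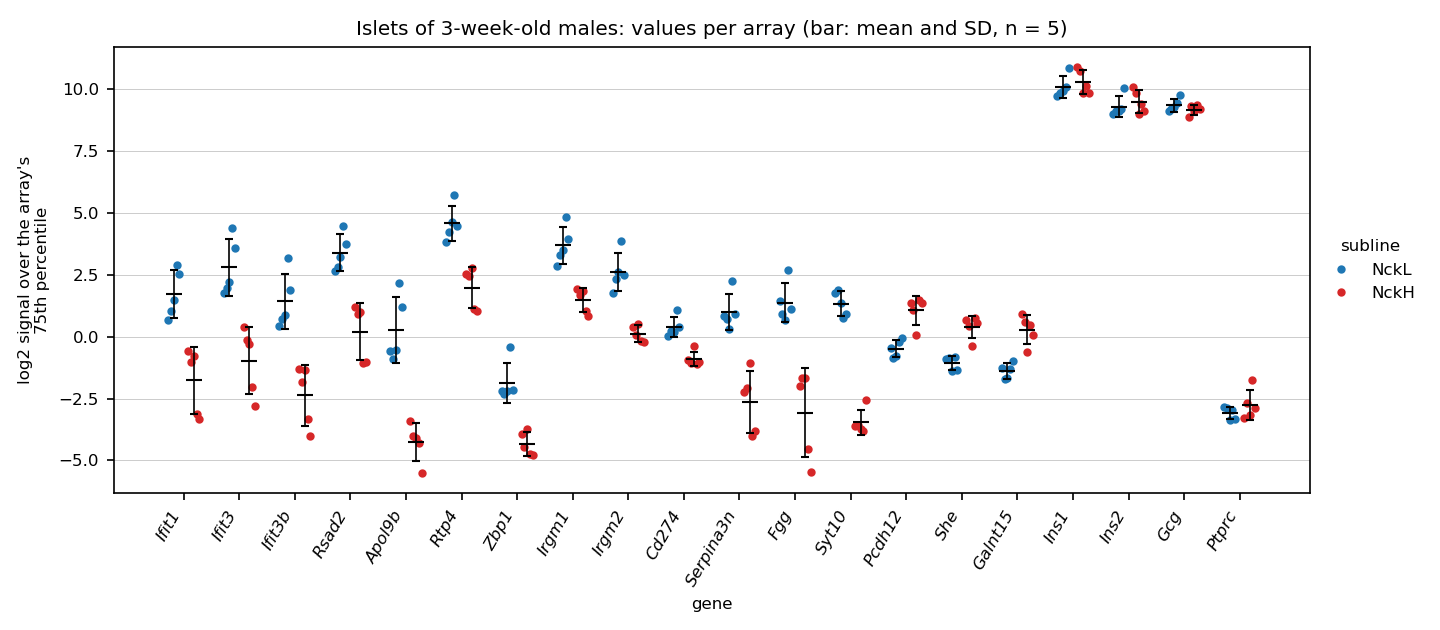
Log2 signal over the array's 75th percentile (vertical axis) of 20 genes (horizontal axis) in islets, with 1 point per array, coloured by subline, and bars for mean and SD (n = 5). The NckH values of Ifit1 and Syt10 lie below every NckL value, while those of Ins1, Ins2, Gcg and Ptprc overlap.

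The islet arrays lay on 2 slides, each with both sublines. The type I interferon score was lower in NckH on slide 1 (−1.38 ± 0.53, 2 NckH and 3 NckL) and on slide 2 (−2.41 ± 0.72, 3 NckH and 2 NckL), with a difference of −1.90 ± 0.46 when slide was a block. All 5 NckH scores lay below every NckL score, so the sign on each slide was fixed and adds no support. The acinar score differed by −1.14 ± 2.84 on slide 1 and by −4.83 ± 1.53 on slide 2. All 30 called genes named by the rule kept their sign on both slides, Syt10 among them (−5.02 and −4.65). The 5 NckH values of each gene lay apart from its 5 NckL values, so these signs were fixed too. With slide as a fixed block 4 genes passed, Syt10 (adjusted p = 0.000625) and Bcas3os2 (adjusted p = 0.0285) among them. For Ifit1 the adjusted p was 0.0886 with the block (difference −3.36 ± 0.66, against −3.50 ± 0.65 without it). All 119 genes that had passed kept their sign with the block, and their differences moved by less than 1 SE (119 of 119; median ratio 0.992), while the SE rose by a median factor of 1.07. An exact permutation test of the interferon score gave a two-sided p of 0.00794, the smallest that the relabellings allow (0.0703 after adjustment over 31 lists). The number of genes that passed depended on single arrays. Without NckL replicates 1, 2, 3, 4 and 5 in turn it was 4, 7, 4, 26 and 289, and without NckH replicates 1, 2, 3, 4 and 5 it was 44, 3, 710, 3 and 6. When arrays were scaled by probes well above background on all of them, the median difference of all genes moved from −0.079 to 0.022 and 57 genes passed, 27 higher and 30 lower, so the excess of falls depended on the scaling.

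The T cell arrays were checked against their labels by sex-linked genes. Of the 20 libraries labelled male, 10 had the Y-linked transcript Ddx3y well above background and 10 had Xist, the RNA of the inactive X chromosome. Of the 20 labelled female, 10 had Ddx3y and 10 had Xist. Ddx3y was at −1.90 or higher on the arrays that had it and at −8.48 or lower on the others, and Fisher's exact test of the label against Ddx3y gave a two-sided p of 1. Each of the 8 groups held 2 or 3 libraries with Ddx3y, 2 in every group labelled 15 weeks and 3 in every group labelled 6 weeks. In the group labelled NckH female of 6 weeks 1 library had both transcripts and 1 had neither. All 10 islet libraries, labelled male, had Ddx3y. Directions by sex below refer to libraries as labelled, and 21 of the 40 carried the transcripts of the other sex or neither transcript.

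**Figure D2:**
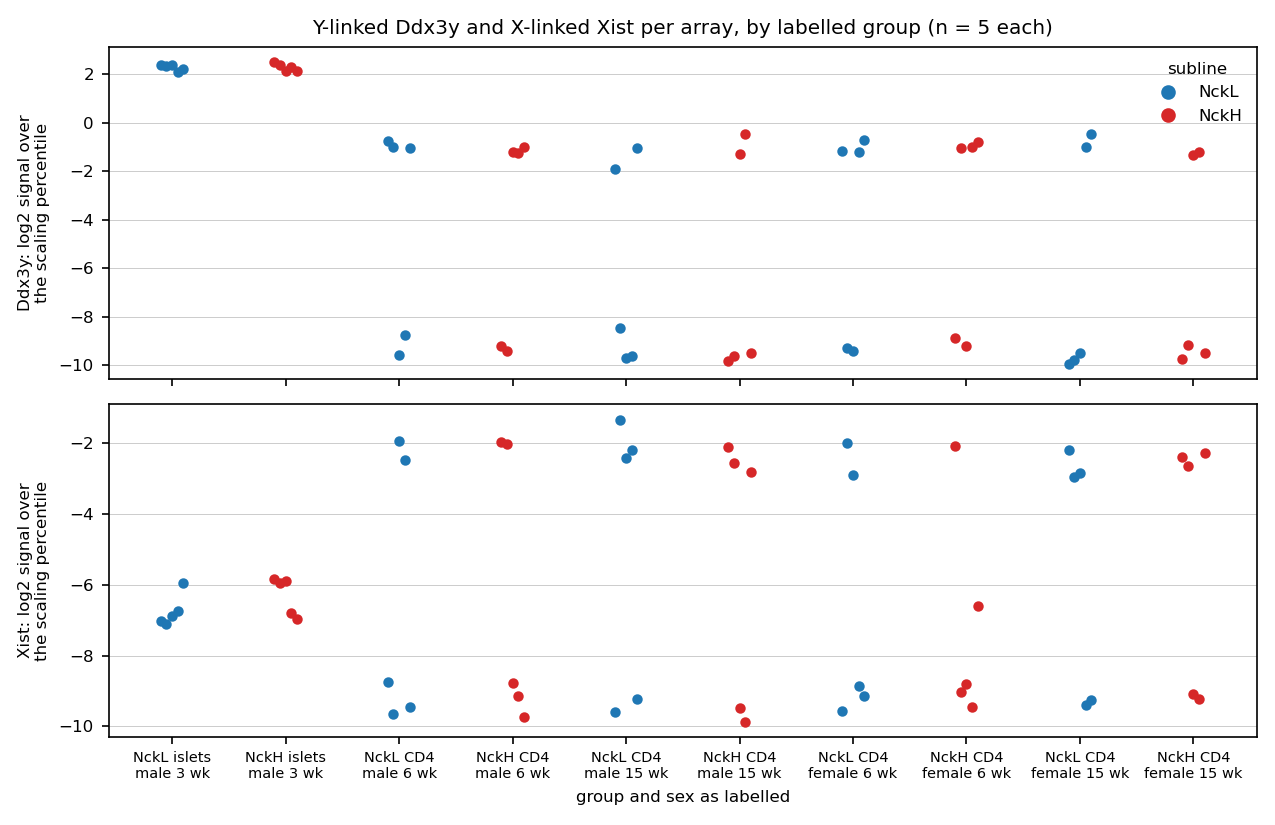
Log2 signal over the scaling percentile (vertical axes) of the Y-linked Ddx3y and the X-linked Xist on each array, by labelled group (horizontal axis, n = 5, coloured by subline). Each T cell group has 2 or 3 arrays with Ddx3y, whatever its labelled sex, and the 10 islet arrays have it.

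A gene that separated the sublines in islets, Rp9 (chosen after its values were seen), was looked at in the same way. Its probe at chromosome 9, 22253254 to 22254260 (mm9, per the array annotation), was at 3.06 ± 0.62 in NckL islets and at −6.61 ± 0.53 in NckH islets. It was on in 5 of 5 NckL and 0 of 5 NckH arrays. In T cells it was on in 14 of 40 libraries, 7 of 20 labelled NckL and 7 of 20 labelled NckH (Fisher's exact p = 1). Values were 0.64 or higher on arrays with the signal and −6.41 or lower on the rest. A brighter Rp9 probe fell by 2.11 ± 0.22 in NckH islets (adjusted p = 0.00851).

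**Figure D3:**
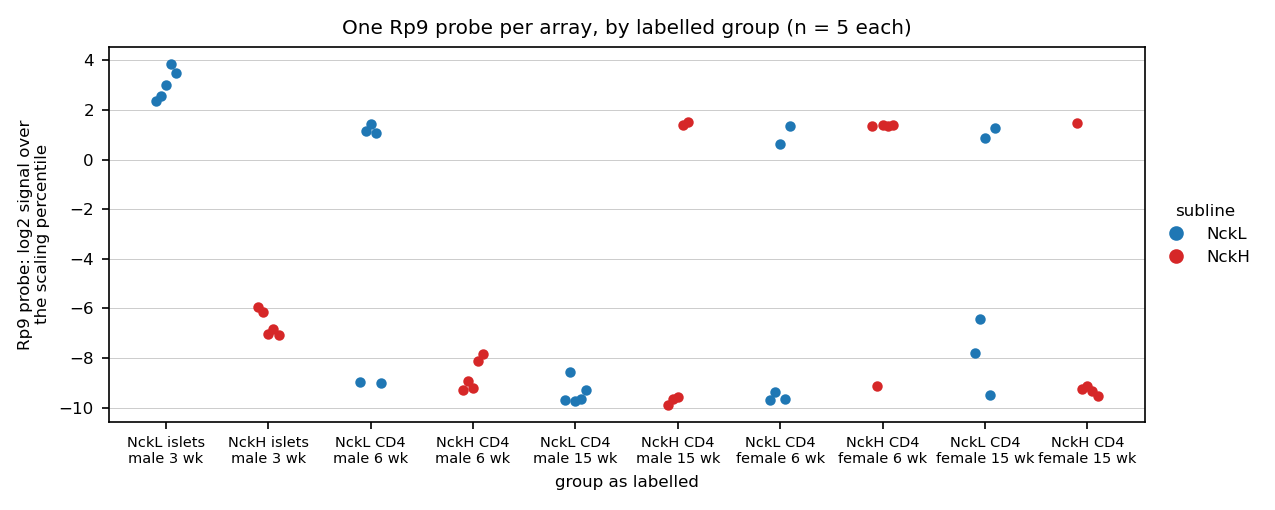
Log2 signal over the scaling percentile (vertical axis) of 1 probe of Rp9 on each array, by labelled group (horizontal axis, n = 5, coloured by subline). The 5 NckL and 5 NckH islet arrays are apart, and T cell arrays with and without the signal occur under both subline labels (7 of 20 each).

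The next comparison asked how splenic CD4 T cells of the sublines differed over both labelled sexes and ages. Tomm22, which encodes a subunit of the mitochondrial import receptor, was lower in libraries labelled NckH (−2.74 ± 0.32 against −2.36 ± 0.22, n = 20 and 20; difference −0.39 ± 0.07, adjusted p = 0.0102). It lay below the NckL mean in 18 of 20 libraries. The unassigned transcripts 2310043M15Rik (0.72 ± 0.12, adjusted p = 0.0102), Gm5106 (0.70 ± 0.14, adjusted p = 0.0341) and Atxn7l1os2 (0.77 ± 0.15, adjusted p = 0.0456) were higher. The signs of Gm5106 and Atxn7l1os2 were not the same in all 4 groups, and Gm5106 turned to −0.25 with slide as a block. A total of 5 genes passed of 13974 tested, while 1746 had an unadjusted p under 0.05 and chance gives 699. H1f8 (adjusted p = 0.0523), Espnl (0.32 ± 0.07, adjusted p = 0.0523), Gm9372 (0.57 ± 0.12), Zfp292 (0.47 ± 0.10) and A230045G11Rik (0.27 ± 0.06) did not pass.

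Of 35 lists tested in T cells, 11 passed for the subline, 6 higher and 5 lower in NckH, and each had an adjusted p = 0.784 with an estimated correlation. All 25 members of the T cell receptor list were higher (mean 0.20, adjusted p = 3.44e-06), led by the phosphatase gene Ptprc (0.34 ± 0.11), Plcg1 (0.24 ± 0.09) and the adaptor gene Lat (0.29 ± 0.12), though no member passed alone (0 in limma). Genes of naive T cells (16 of 18 higher, mean 0.20), with Cd27 (0.34 ± 0.11) and Tcf7 (0.32 ± 0.12), and of follicular helper T cells (15 of 16, mean 0.18) shifted the same way, as did migration and adhesion (20 of 23, mean 0.13, S1pr1 0.32 ± 0.15). The type I interferon list, lower in NckH islets, was higher here (28 of 32 members, mean 0.10, adjusted p = 0.00653). Xaf1 (0.39 ± 0.10) was higher and Rsad2 (−1.05 ± 0.31) lower, neither passing, and adjusted over the list alone 1 member was higher and 1 lower. The MHC class I list followed it (21 of 23, mean 0.10). All 12 erythroid genes were lower (mean −1.38, adjusted p = 4.17e-09), with Hbb-b2 at −2.08 ± 0.62, and so were all 27 cell cycle genes (mean −0.40, adjusted p = 1.52e-08), such as Mcm5 (−0.45 ± 0.21). Platelet genes (8 of 8, mean −0.59, Pf4 −1.27 ± 0.61), antioxidant defence (19 of 21, mean −0.20) and oxidative phosphorylation (28 of 33, mean −0.09, Atp5o −0.37 ± 0.10) were lower too. With slide as a block the T cell receptor (−0.0231), follicular helper (−0.40), MHC class I (−0.0898), migration (0.0028) and platelet (−0.000768) lists turned their direction in the test. Then 6 lists passed, 0 higher and 6 lower, and only oxidative phosphorylation was among the 11. Only 1 T cell slide held both sublines and links them under the block, so lost precision could give these changes too. Single libraries carried part of the list shifts by subline. Without NckL replicate 2 labelled female of 6 weeks the means were 0.0445 for MHC class I, 0.0660 for migration and 0.121 for follicular helper genes, none of which then passed. They were 0.115 for naive genes, 0.13 for the T cell receptor and −0.26 for the cell cycle, which still did. Genes of other cells were present in the T cell libraries to varying degrees. The haemoglobin gene Hba-a1 ranged from −1.92 to 6.32, and the B cell gene Cd79a was well above background on 40 of 40 arrays. So was the CD8 T cell gene Cd8a, which was at 0.59 ± 0.68 where Cd4 was at 2.97 ± 0.48. The islet hormone genes Ins2, Ins1 and Gcg were well above background on 31, 17 and 13 of the 40. Whether the share of other cells gave the list shifts by subline, age or labelled sex was not tested.

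**Figure D4:**
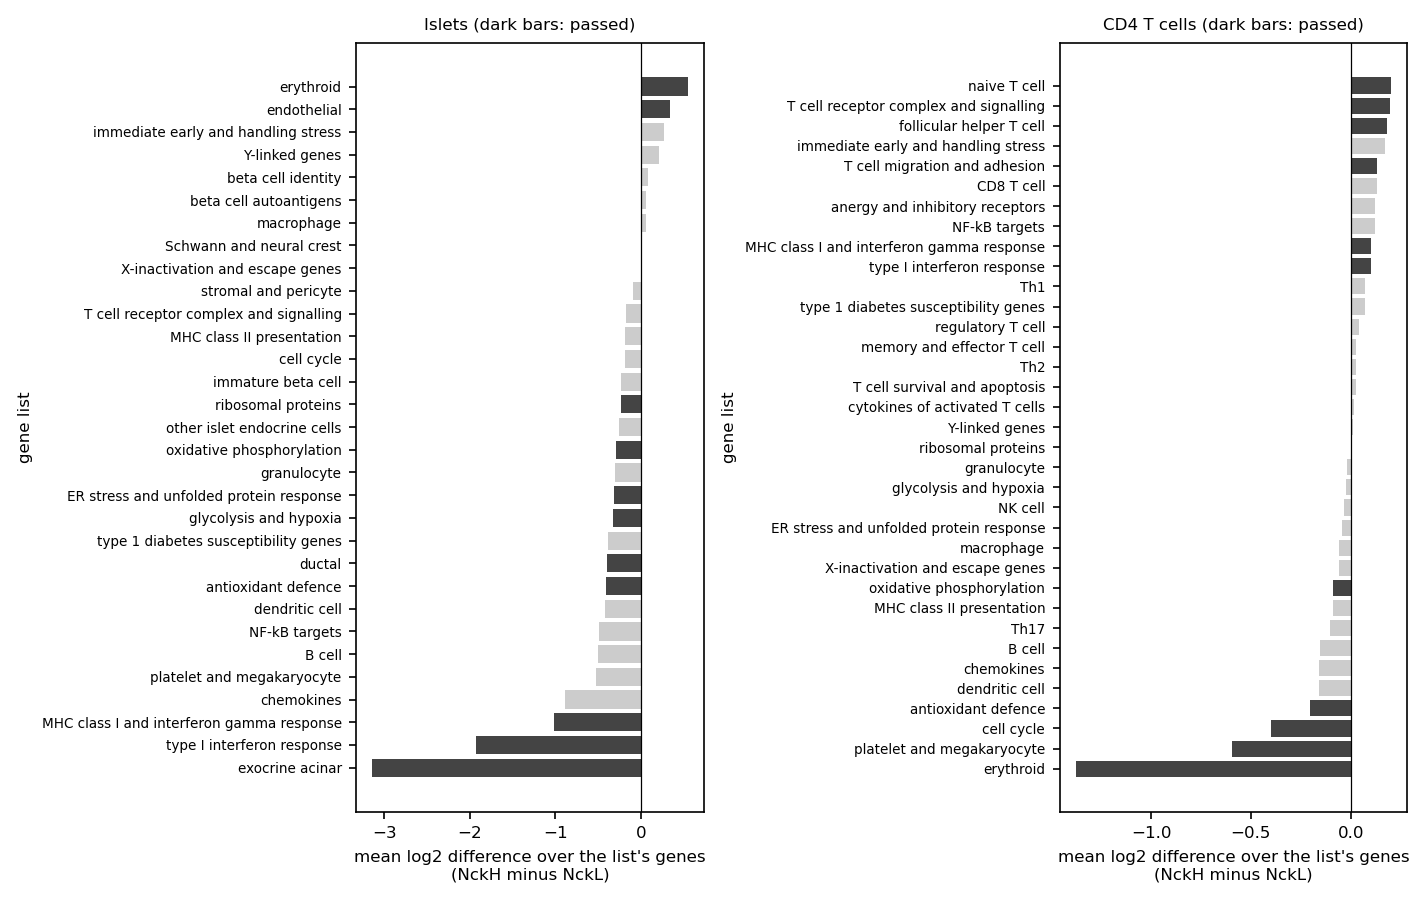
Mean log2 difference, NckH minus NckL, over the genes of each fixed list (horizontal axes; 1 bar per list) in islets (left, 31 lists) and CD4 T cells (right, 35 lists), with dark bars for lists that passed with a preset correlation. The type I interferon list is at −1.93 in islets and 0.10 in T cells, and the erythroid list at 0.55 and −1.38.

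The T cell sublines were also compared within each labelled sex and age. Among libraries labelled female of 15 weeks 26 genes passed, 7 higher and 19 lower in NckH, 12 of them at least 2-fold (6 and 6), and 999 had an unadjusted p under 0.05. The mitochondrial genes Tomm22 (−0.81 ± 0.13, adjusted p = 0.00768), Mrps14 (−1.08 ± 0.20, adjusted p = 0.0214) and Ndufa8 (−0.83 ± 0.16, adjusted p = 0.0214) had the smallest p, and 2 other probes of Mrps14 did not follow (0.0831 ± 0.16 and 0.84 ± 0.34). Without NckL replicate 5 or NckH replicate 4 of these groups 0 genes passed, and without NckL replicate 1 there were 76. Without NckL replicates 2, 3 or 4 or NckH replicates 3 or 5 it was 1, and without NckL replicate 2 labelled male of 15 weeks it was 44. In the groups labelled male of 6 weeks, male of 15 weeks and female of 6 weeks 0 genes passed in limma, with 1139, 610 and 350 at an unadjusted p under 0.05. For the groups labelled male of 6 weeks, genes passed once single arrays were left out. There were 17 and 13 without NckH replicates 5 and 1 of these groups and 3 without NckL replicate 4. Without other T cell arrays there were 13 and 9 (NckL labelled female of 6 weeks, replicates 3 and 2), 5 and 5 (NckL labelled male of 15 weeks, replicates 1 and 5), 2 (NckL labelled female of 15 weeks, replicate 5) and 1 (NckH labelled female of 6 weeks, replicate 3). The interaction of subline with age, the difference between ages in the subline effect, was called for 0 genes in limma (556 at an unadjusted p under 0.05). Cops8 (0.45 ± 0.11) and Gm20939 (−0.64 ± 0.18) were among the genes with the smallest p there, and neither passed. The interaction of subline with labelled sex was called for 0 genes as well (555 at an unadjusted p under 0.05), with Commd2 (−0.81 ± 0.18), Dbt and 2310081J21Rik (−1.35 ± 0.31) first.

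Only slide 8 held T cells of both sublines, 3 libraries labelled NckH (male) and 4 labelled NckL (female). The other T cell slides held 1 subline each. With slide as a fixed block 0 genes passed for the subline in limma (152 at an unadjusted p under 0.05), and on slide 8 alone 0 passed (866 at an unadjusted p under 0.05). The block links the sublines through slide 8 only, so this loss of calls cannot tell an effect of slide from lost precision. Leaving out single T cell arrays gave 2 to 16 genes. There were 16 without NckL replicate 2 labelled male of 15 weeks, 9 without NckL replicate 5 labelled female of 15 weeks and 8 without NckH replicate 4 labelled female of 6 weeks. There were 3 without NckL replicate 5 labelled male of 6 weeks, NckH replicate 4 labelled male of 15 weeks or NckH replicate 1 labelled female of 15 weeks. There were 2 without NckL replicates 1, 3 or 4 labelled male of 15 weeks, 1 or 3 labelled female of 6 weeks or 1 labelled female of 15 weeks. The count was also 2 without NckH replicates 2, 3 or 4 labelled male of 6 weeks, 2 or 3 labelled male of 15 weeks, 1 labelled female of 6 weeks, or 2 or 5 labelled female of 15 weeks.

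Age was compared as labelled, at 15 against 6 weeks. As sex-linked transcripts did not follow the labels of these libraries, the age groups could be mixed too. Of 35 lists 18 passed (7 higher, 11 lower), and all 18 lists below had an adjusted p of 0.784 or, for the T cell receptor, 0.794 with an estimated correlation, so that 0 passed with it. Genes of the immediate early response were lower in libraries labelled 15 weeks, where all 22 members of the list had negative differences (mean −0.58, adjusted p = 3.88e-13, and adjusted p = 0.784 with an estimated correlation). Ier2 (−0.54 ± 0.14), Jun (−0.62 ± 0.18) and Egr1 (−0.68 ± 0.22) led the list without passing alone, and adjusted over the list alone 9 members were lower. The NF-kB list was lower in 16 of 16 members (mean −0.27, Nfkbiz −0.42 ± 0.13, 1 lower adjusted over the list alone). All 27 cell cycle genes (mean 0.35), all 12 erythroid genes (mean 0.98, Hbb-b1 1.38 ± 0.61) and all 8 platelet genes (mean 0.51) were higher, each with an adjusted p of 0.784 with an estimated correlation. Oxidative phosphorylation (mean 0.07, Uqcrb 0.17 ± 0.06), antioxidant defence (0.19, Prdx1 0.18 ± 0.09), NK cell genes (0.14, Ncr1 0.55 ± 0.22) and X-linked escape genes (0.31) were higher. Naive T cell genes (−0.11, Foxo1 −0.22 ± 0.11), regulatory T cell genes (−0.16, Foxp3 −0.33 ± 0.18), anergy genes (−0.19, Nr4a1 −0.81 ± 0.34), cytokines (−0.20, Ifng −0.67 ± 0.28), the T cell receptor (−0.07), MHC class I (−0.10), diabetes susceptibility (−0.09) and Y-linked lists (−1.30) were lower. Ribosomal genes were lower (−0.07, Rps24 −0.18 ± 0.07), but turned to 0.0075 after quantile normalisation. Ddx3y was on in 8 of 20 libraries of 15 weeks and 12 of 20 of 6 weeks. Without the 21 libraries that carried the transcripts of the other sex or neither transcript, the naive (0.0706), regulatory (0.0221), X-linked (−0.0540), T cell receptor (−0.00343), anergy (−0.0075) and cytokine (−0.11) lists turned their direction in the test. NK cell genes were at 0.0843 without NckL replicate 2 labelled male of 15 weeks and naive genes at −0.0692 without NckL replicate 1 labelled female of 6 weeks, and neither then passed. For age 0 genes passed (0 of 13974 in limma, 845 at an unadjusted p under 0.05). E130119H09Rik (−0.91 ± 0.17, adjusted p = 0.105), 9330175M20Rik (−0.29 ± 0.06), Slc4a9 (−0.33 ± 0.08) and Tlr9 (−0.30 ± 0.08) had the smallest p together with Brdt (−0.33 ± 0.08), whose other probe was at 0.0245 ± 0.19.

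The sexes were compared as labelled, female minus male, and the balance of Ddx3y in both labels applies to every direction given here. Dll3, which encodes a Notch ligand, was lower in libraries labelled female (adjusted p = 0.00222). It was well above background in 2 of 20 libraries labelled female and 15 of 20 labelled male, and Plet1, a surface protein gene, in 1 of 20 and 9 of 20 (adjusted p = 0.0482), so the size of these falls was not estimated. The zinc finger gene Zfp995 was lower by 0.43 ± 0.09 (adjusted p = 0.0482). Atxn7l1os2 was higher under the female label (0.92 ± 0.15, adjusted p = 0.00639), as were Hs1bp3 (0.29 ± 0.06) and the deubiquitinase gene Usp21 (0.25 ± 0.05). Supt6, which encodes a histone chaperone, was higher by 0.20 ± 0.04, but its other probe had the opposite sign and the mean of its probes was at −0.21. These were all 7 genes that passed (4 higher, 3 lower), while 3158 of 13974 had an unadjusted p under 0.05. Rab7 (−0.37 ± 0.08, adjusted p = 0.0552), 4930506C21Rik (0.65 ± 0.14) and Gm3893 did not pass, nor did Xist (−0.26 ± 1.15) or Ddx3y (0.02 ± 1.40).

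Of 35 lists, 18 passed for the labelled sex (12 higher, 6 lower in libraries labelled female). Their adjusted p was 0.784 or, for the immediate early list, 0.791 with an estimated correlation, so 0 passed. All 27 cell cycle genes (mean −0.49, adjusted p = 3.44e-06, Mki67 −0.70 ± 0.31), all 12 erythroid genes (mean −1.26, Rhag −1.84 ± 0.60) and all 8 platelet genes (mean −0.95, Itga2b −0.91 ± 0.29) were lower under the female label. Adjusted over the list alone 5 erythroid and 6 platelet genes were lower. Dendritic cell (−0.47), B cell (−0.30, Bank1 −0.59 ± 0.24) and antioxidant genes (−0.26, Nqo1 −1.28 ± 0.49) were lower as well. The T cell receptor list was higher in 24 of 25 members (mean 0.17, adjusted p = 0.000101, Cd4 0.42 ± 0.14, Zap70 0.21 ± 0.08). Anergy and inhibitory receptor genes were higher in 18 of 21 (mean 0.22, Lag3 0.41 ± 0.13, 3 higher adjusted over the list alone). Follicular helper genes (0.26, Cd40lg 0.51 ± 0.18), MHC class I (0.16, Psme1 0.17 ± 0.07), cytokines (0.19, Tgfb1 0.17 ± 0.06), naive genes (0.13, Il6ra 0.22 ± 0.08) and NF-kB targets (0.16, Bcl3 0.30 ± 0.11) were higher. So were the diabetes susceptibility (0.11, Cd101 0.41 ± 0.13), memory (0.11, Crip1 0.18 ± 0.08), immediate early (0.24, Jund 0.36 ± 0.18) and migration lists (0.10, Itga4 0.33 ± 0.09, whose other probe had the opposite sign). Ribosomal genes were higher (mean 0.07, Rps15 0.15 ± 0.06), but turned direction in the test after quantile normalisation (0.0038), with slide as a block (−0.013) and in the authors' table (0.0040). With slide as a block the follicular helper (−0.0806) and immediate early lists (0.0314) turned in the test too, and without NckL replicate 5 labelled female of 15 weeks the latter was at 0.15 and did not pass.

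The count for the labelled sex changed with single arrays. It was 3137 without NckL replicate 2 labelled female of 6 weeks, 455 without NckL replicate 1 labelled female of 15 weeks, 161 without NckL replicate 2 labelled male of 15 weeks and 64 without NckL replicate 2 labelled male of 6 weeks. It was 15 without NckL replicate 5 labelled male of 15 weeks or NckH replicate 1 labelled female of 6 weeks, and 14 without NckH replicate 3 of the latter group. It was 4 without NckL replicate 3 labelled female of 15 weeks or NckH replicate 4 labelled male of 6 weeks, and 3 without NckH replicate 1 labelled male of 6 weeks or NckH replicate 4 labelled female of 6 weeks. The count was 2 without NckL replicates 1, 3 or 5 labelled male of 6 weeks, 1, 3 or 4 labelled male of 15 weeks, 1, 3, 4 or 5 labelled female of 6 weeks, or 4 or 5 labelled female of 15 weeks. It was also 2 without NckH replicates 2, 3 or 5 labelled male of 6 weeks, 1, 2 or 3 labelled male of 15 weeks, 5 labelled female of 6 weeks, or 2, 3, 4 or 5 labelled female of 15 weeks. With slide as a fixed block 0 genes passed in limma (264 at an unadjusted p under 0.05), and scaling by all probes gave 618 (557 higher, 61 lower).

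The genes called for the subline in islets were compared with those called in T cells. Of 13015 genes tested in both, 79 passed in islets and 4 in T cells, and 0 were shared, where independent lists give 0.0243 (Fisher's exact p = 1, two-sided). With so few expected, an overlap of 0 decides nothing about shared subline effects. Of the 79, 33 had the same sign in T cells, and 15 had an unadjusted p under 0.05 there, where 1746 of all 13974 T cell genes had. Over the 13015 genes the differences of the 2 tissues had a Spearman correlation of 0.16. The T cell genes Cd4 (0.21 ± 0.14) and Cd3e (0.25 ± 0.11) did not pass between sublines. The same was true of Cd8a (0.23 ± 0.21), of Foxp3 (−0.13 ± 0.18) and Il2ra (−0.11 ± 0.20), which mark regulatory T cells, and of Cd44 (0.11 ± 0.05).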

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

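The tests of sex-linked transcripts and of Rp9, and those of slide, acinar genes, dendritic cells, B cells and granulocytes for the islet interferon response, were chosen after the result was seen, whereas the test of macrophages and the splits of the samples were chosen before.

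Sex-linked transcripts did not follow the labelled sex of the T cell libraries. Failed probes are argued against by the 2 Xist probes and the Y-linked genes Ddx3y, Eif2s3y and Uty, which gave the same reading on 40 of 40 arrays, and mixed male and female cells by the 1 array with both signals. The dimmer Y-linked gene Kdm5d, well above background on 14 of 40 arrays, was not part of this reading. Mislabelled samples stay open as a candidate explanation, since 20 of 40 libraries had Ddx3y under a female label or lacked it under a male one. No value tells which libraries these are for age or subline, and no biological explanation was tested.

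Rp9 was on in every NckL islet library and off in every NckH one, yet on in 7 of 20 T cell libraries labelled NckH and 7 of 20 labelled NckL. A failed probe is argued against by a second Rp9 probe and one of the neighbouring 9530077C05Rik, which followed on 40 of 40 arrays. Labels exchanged among the 40 T cell libraries alone would give 20 libraries with the signal, as 20 are labelled NckL, where 14 had it. This count holds only if Rp9 is fixed within each subline. With a variant that segregates, it decides nothing, and an exchange among the 40 stays open. Ddx3y was on in 20 of 40 libraries, where 20 are labelled male, a number that such an exchange would give. Mislabelled samples from a wider set (Fisher's exact p = 1 for signal against label) and a variant that segregates within the sublines (7 libraries labelled NckH with the signal) may each give this pattern and stay open. In each of these cases the T cell subline differences could be those of mixed groups.

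The type I interferon score was lower in NckH islets by −1.93 ± 0.42, and in T cells it differed by 0.10. Macrophages in the islet preparation are argued against by a median difference of 0.0047 over 17 macrophage genes (interval −0.307 to 0.267), slide by −1.90 ± 0.46 with slide as a block, and acinar carry-over by −1.89 ± 0.56 with the acinar score as a covariate. Dendritic cells (median −0.61 over 7 genes, interval −1.01 to 0.54), B cells (−0.53 over 8, −2.64 to 0.84) and granulocytes (−0.37 over 4) stay open, since their genes are too few. These intervals are over the genes of a list, read on the same arrays, so they do not cover variation between arrays. Per array, the macrophage score was at 0.13 to 0.31 in NckH and −0.29 to 0.38 in NckL. NckH replicates 4 and 5 had the lowest interferon scores (−0.42 and −0.65) and immediate early scores of 5.01 and 5.10, where the other islet arrays had 3.32 to 4.21. Without them the interferon list was lower by 1.56, and 1 gene passed where 119 had. Handling of these samples was not tested and stays open, as does a difference of the sublines in interferon signalling. Litter or cage, which no label gives, could not be tested.

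Differences between tissues were tested by permuting sublines within tissues (10000 permutations, 22 lists, 4 passing). The NckH minus NckL score in islets minus that in T cells was −2.03 for type I interferon (adjusted p = 0.0110), 1.93 for erythroid genes (adjusted p = 0.0110), −1.12 for MHC class I (adjusted p = 0.0192) and −0.46 for diabetes susceptibility genes (adjusted p = 0.0192). Tissue was confounded with age and scan day. The T cell part rests on subline labels that Rp9 did not follow, so mislabelled T cell libraries, which stay open, could have shrunk it. The permutations did not keep slides together, and in T cells subline was confounded with slide on all slides but 1. With slide as a block the T cell erythroid difference was −0.68 where it was −1.38 without, so slide stays open for the erythroid result. Without NckH replicates 4 and 5 the islet erythroid difference was 0.31 where it was 0.55 with them.

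Samples far from the others of their group (a gap over 0.71 of the range) were found in 1 of 20 groups for array measures, 14 of 110 for list scores and 9 of 100 for called genes, where chance gives about 1 in 20. NckL islet replicate 5 had a log2 75th percentile of 7.81 and scores of 3.66 for antioxidant, 3.16 for glycolysis, 4.78 for oxidative phosphorylation and 6.98 for ribosomal genes. NckH islet replicate 3 was at −0.38 for Cd274, 0.0593 for Pcdh12, −0.37 for She and 3.79 for the antioxidant score. NckL islet replicate 4 was at −0.0675 for Steap4 and −0.43 for Zbp1, and NckH islet replicate 5 at −2.58 for Syt10. Among T cells, NckL replicate 2 labelled female of 6 weeks had scores of −0.11 for MHC class I, −0.19 for migration, 0.59 for the T cell receptor, 1.12 for antioxidant, 0.75 for cell cycle and −0.37 for naive genes. Single T cell libraries stood apart at −5.18 for Atxn7l1os2 (NckH labelled male of 6 weeks, replicate 5) and −6.70 for Gm5106 (NckL female of 15 weeks, replicate 1). Others did so at −1.18 for type I interferon (NckH female of 6 weeks, replicate 5), 1.96 for oxidative phosphorylation (NckL female of 15 weeks, replicate 5) and −0.58 for follicular helper genes (NckL male of 15 weeks, replicate 5).

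Probes matched to no gene, which no comparison used, also held calls. In limma 101 of 9230 passed for the islet subline (62 higher, 39 lower). For the T cell subline 100 of 9242 passed (92 higher, 8 lower), and for the labelled sex 238 of 9242 (148 higher, 90 lower). Among the 13974 genes tested in T cells 5 and 7 had passed, so calls were more frequent among the unmatched probes. The cause of this was not tested.

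Other splits of the samples were drawn, 100 per result. Splits as large as the real one, itself included, were few for the islet genes (119, 2 splits as large, highest other 4537) and the T cell subline (5, 1 split, highest other 1). They were also few for the labelled sex (7, 2 splits, highest other 7) and the groups labelled female of 15 weeks (26, 1 split, highest other 8). For each count taken alone this argues against chance. It does not exclude chance, as several counts were tested without adjustment. The splits did not keep slides apart, and all T cell slides but 1 held a single subline. With slide as a fixed block 0 genes passed for the T cell subline, the labelled sex and the groups labelled female of 15 weeks, so slide stays open for these counts. In islets 4 passed. Slide as the whole cause is argued against by the layout, with 2 NckH and 3 NckL arrays on slide 1 and 3 NckH and 2 NckL on slide 2. Each of the 119 genes kept its sign with a difference moved by less than 1 SE. With this layout, and genes chosen in the same data, such small moves add little. The SE rose by a median factor of 1.07, and why the calls ended was not tested. A split with 4537 genes points to a structure of the islet samples other than the subline, and the split of the 2 slides gave 0 genes. Principal component 1, the main axis of variation (46.2%), set apart the 3 dimmest arrays. These were NckH replicates 1 (78.4) and 2 (58.7) and NckL replicate 5 (54.0). Component 2 (32.9%) set apart NckH replicates 4 (71.8) and 5 (67.6). Which of these the split followed was not tested. Chance cannot be excluded for the lists that passed in islets (11, 29 splits, highest other 15) or T cells (11, 63 splits, highest other 25). The split of the islets by slide passed 14 lists, and with slide as a block 10 lists passed for the subline. For results of 0 the splits decide nothing, as every count is at least 0 and all 100 splits were as large by construction: age (highest other 1), the interactions with age (57) and sex (1656), the shared genes (0), and the groups labelled male of 6 weeks (1), male of 15 weeks (1155) and female of 6 weeks (3). The splits with 1656 and 1155 genes point to a structure of the T cell samples.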

How the results depend on the processing

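The alternatives that left out islet libraries that stood apart, dim islet arrays, and T cell libraries against their labelled sex were chosen after seeing the data. The number of arrays and a share of 42.9% to 58.2% of spots above background limit what can be called, and the cause of a change was not tested unless fewer samples or genes give it. Counts that moved over 1.5 times are given with the main counts being 119 for islets, 11 for islet lists, 5 for the T cell subline, 26 for female of 15 weeks, 7 for labelled sex, 11 for T cell lists and 0 elsewhere. Normexp background gave 22 for islets (2 higher, 20 lower), 2 for the subline, 8 for female of 15 weeks and 0 for sex (2638 at an unadjusted p under 0.05 in limma). The other percentile gave 57 (27 higher, 30 lower), 3 for the subline and 618 for sex (557 higher, 61 lower). Quantile normalisation gave 3 for the subline and 15 for sex (12 higher, 3 lower), and turned the ribosomal list in the test for age (0.0075) and sex (0.0038). No detection filter gave 18 for islets, 14 for female of 15 weeks and 3 for sex, and a filter at 50% of arrays 8 for the subline and 1 for sex. The mean of probes gave 3 for the subline, 14 for male of 6 weeks, 45 for female of 15 weeks and 23 for sex, and turned Supt6 (−0.21), and every probe on its own 103 for female of 15 weeks and 57 for sex. Array weights gave 7338 for islets, 17 islet lists, 81 for the subline, 28 for male of 6 weeks, 77 for male of 15 weeks, 227 for female of 15 weeks, 4051 for age, 5146 for sex, 23 for the interaction with sex and 29 shared genes. With the replicate number as a block 1 gene passed in islets and 9 for male of 6 weeks, and it moved no other count by over 1.5 times. The numbers did not pair the samples (mean correlation −0.176 in islets and 0.036 in T cells, closest library with the same number for 2 of 10 and 12 of 40). Slide as a fixed block gave 4 for islets, 6 T cell lists (0 higher, 6 lower, 1 of them among the 11), and in limma 0 for the subline (152 at an unadjusted p under 0.05), female of 15 weeks (233) and sex (264). It turned Gm5106 (−0.25) and, in the direction of the test, the subline lists of MHC class I (−0.0898), T cell receptor (−0.0231), platelets (−0.000768), follicular helper cells (−0.40) and migration (0.0028), and the sex lists of follicular helper cells (−0.0806), immediate early (0.0314) and ribosomal genes (−0.013). Slide as a random block gave 2 for sex. The authors' table gave 3 for the subline, 15 for female of 15 weeks and 3 for sex, and turned Supt6 (−0.18) and, in the test, the ribosomal list for sex (0.0040). A log2 change of at least 1 left 0 for the subline (1746), 12 for female of 15 weeks and 2 for sex. An estimated correlation left 0 lists in islets and 0 in T cells, and fry left 0 in T cells. Only the 2 groups in the fit gave 0 for female of 15 weeks (1257). Islets of slide 1 gave 0 (346) and of slide 2 gave 0 (2993) genes and 7 lists. The slide with both sublines gave 0 for the subline (866) and turned Atxn7l1os2 (−0.39). Without NckH islet replicates 4 and 5, 1 gene passed, and without the 3 dimmest arrays 30 passed, 7 of them shared with the 119. Without libraries against their labelled sex 1 passed for the subline, 0 for female of 15 weeks (220) and 18 T cell lists. The age lists of T cell receptor (−0.00343), naive (0.0706), regulatory (0.0221), anergy (−0.0075), cytokines (−0.11) and X-linked genes (−0.0540) turned in the test. Leaving out 1 library gave 3 to 710 genes in islets and 9 to 16 islet lists, 2 to 16 for the subline, 0 to 17 for male of 6 weeks, 0 to 1 for male of 15 weeks, 0 to 1 for female of 6 weeks, 0 to 76 for female of 15 weeks, 0 to 1 for age, 2 to 3137 for sex, 0 to 1 for each interaction, 8 to 14 T cell lists and 0 to 0 shared genes. None of the 11 islet lists that passed turned its direction in the test under any of these alternatives (209 values, 170 of them on the same side of the threshold). Nor did any named islet gene that had passed, when taken by its brightest probe or the mean of its probes. Named genes that had not passed could turn, such as Ptprc, at 0.33 over all islets and −0.0424 on slide 1.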
